A study of Mus musculus with 3 samples.

How the data were processed

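Back-skin epidermis of wild-type C57BL/6 mice, 7 weeks old and in the second resting phase (telogen) of the hair cycle, was separated from the dermis with thermolysin (0.25 mg/ml for 1 hour) and sorted by flow cytometry with antibodies against CD34 and integrin alpha 6 (Itga6), per the labels' protocols. The CD34-negative cells are called N, the CD34-positive cells with high Itga6 (basal bulge stem cells) B, and the CD34-positive cells with low Itga6 (suprabasal bulge stem cells) S. The bulge is the part of the hair follicle that holds its resting stem cells. Per the labels' protocols, RNA of 4 mice was pooled for each population, amplified isothermally from poly(T) and random primers because little RNA was obtained, made into Nextera XT libraries and sequenced with paired-end reads of 75 bp. There was thus 1 library for each of 3 groups.

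The files hold FPKM values (fragments per kilobase of transcript and per M mapped fragments, M for mega) per Ensembl gene that the authors deposited, with gene positions. The header says FPKM for N and S. For B the column carries the name of the population, and the unit was taken from the values, which step by a fixed amount per fragment and kilobase, as in N and S with an amount of their own, and follow the same gene rows. TopHat2 2.0.12, Cufflinks 2.1.1, DESeq2 and the build mm10 are named in the submitters' processing notes, with no role given for any of them. The annotation and the read filters are not given in the sources used here. Each file holds 49452 rows and no error, interval or status per gene. Gene symbols were found for 49195 rows, 49109 of them in a table of gene names and the rest in GENCODE M21, and 257 rows had none. Of the rows in GENCODE M21, 91.5% had the same chromosome, start and end there. Coordinates are given as in the files (1-based, mm10).

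Preamplification from both poly(T) and random primers retains ribosomal and other non-polyadenylated RNA, and short transcripts receive inflated FPKM values. Mitochondrial ribosomal RNA held 28.5% of the summed FPKM in N, 11.1% in S and 32.3% in B. Its summed deposited FPKM was 218154 in N, 264552 in S and 193528 in B, so S was highest by that measure. A single mitochondrial tRNA gene of the S library, mt-Tl1, had a deposited FPKM of 1686680 and was listed at 0 in N and B. Mitochondrial tRNA held 71.0% of the summed FPKM in S, so totals could not serve for scaling.

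Depth was read from the steps between low values of genes with 1 exon and at least 3000 bp. The steps correspond to 35.3 M fragments in the FPKM denominator for N, 31.2 M for S and 32.7 M for B. Between 95.7% and 96.2% of the values below 10 fragments lay within 0.1 of a whole fragment, against 20.0% by chance. A transcript of 2 kb at 1 FPKM rests on 70.6 fragments in N, 62.4 in S and 65.5 in B, which gives a counting SD of 11.9% to 12.7%, and of 3.76% to 4.00% at 10 FPKM. These figures cover counting error only and leave out amplification and the differences between mice.

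Rows of 1 symbol were summed. The values were divided by median-of-ratios factors over the 18559 genes above 0 in all 3 libraries (1.10 for N, 0.923 for S and 0.981 for B) and are called scaled FPKM. Genes with a mean of at least 1 were kept, which left 11575 genes, 9916 of them protein coding. The log2 ratio was taken of scaled FPKM plus a pseudocount of 1, and understates the difference for low genes. A gene counted as higher or lower at a log2 ratio of at least 1 in size (2-fold on that scale). With 1 library per group there was no test, and no p-value or standard error is given. A difference describes these libraries and has no replicate check.

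The 3 comparisons, the rule for counts, the 33 gene lists and the rule for named genes were fixed before the data were examined. For each list with at least 4 measured genes (24 lists), the median log2 ratio was placed among 10000 random lists of the same size matched on mean level in 20 bins, and a list is said to stand apart at or below the 2.5th or at or above the 97.5th percentile. Named genes are Cd34 and Itga6, the 10 genes with the largest log2 ratio per comparison and direction among those of at least 10 scaled FPKM in the higher library (without predicted models, small RNAs, ribosomal protein pseudogenes and mitochondrial genes), up to 4 members of each list with the largest ratio among those with a mean of at least 5, and the most abundant member of each list for another cell type. Genes named outside this rule are said to be so. Lists share some genes, such as Dkk3 and Sfrp1 (bulge stem cell genes and Wnt inhibitors), Gas1 (bulge and Hedgehog) and Dsg1a (differentiation and desmosome). The genes of the sort antibodies are list members too, Cd34 of the bulge stem cell list and Itga6 of the basement membrane and hemidesmosome list.

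The size rule and the list percentile were tested on simulated libraries in which 200 genes of the first population were raised by a known factor over the second. Percentages are of the raised genes that passed the filter on the mean, between 185 and 197 of the 200 per run. Of those raised 3-fold the rule called 93.6% for B versus N (11535 genes run). It called 96.4% for S versus N (11526 genes) and 91.8% for S versus B (11361 genes). Of those raised 8-fold it called 100.0% in each comparison (11524, 11550 and 11351 genes). It called 0 of those raised 1.2-fold in each comparison (11527, 11526 and 11333 genes). Between 1 and 5 unchanged genes were called per run. A list of 12 raised genes lay at percentile 100.0 in every run, also at 1.2-fold, so a list can stand apart on a small shift. The other genes of these simulated libraries varied by counting error alone, less than those of the 3 libraries compared here.

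The alternatives were the values as deposited, upper-quartile scaling, rescaling to the same total, pseudocounts of 0.1 and 5, no filter and a mean of at least 5, the highest row per symbol, leaving out predicted models, small RNAs and mitochondrial genes, and a 4-fold threshold. An alternative with intervals was planned and was not run because the files give none. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.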

Results

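The data were FPKM values per gene from 3 RNA sequencing libraries of sorted mouse back-skin epidermis: CD34-negative cells (N), basal bulge stem cells (B, CD34-positive with high Itga6) and suprabasal bulge stem cells (S, CD34-positive with low Itga6). Each library came from RNA pooled from 4 mice, so n was 1 per group and no difference below has a replicate error. Depth was 35.3 M fragments (M for mega) for N, 31.2 M for S and 32.7 M for B. The comparisons address how the stem cells of the bulge differ from the other cells of the epidermis, and how its outer (basal) and inner (suprabasal) layers differ from each other. All levels are scaled FPKM in 1 library.

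The genes of the sort antibodies were looked at first. Cd34, on chromosome 1 (194938819 to 194961279, mm10, ENSMUSG00000016494), had a level of 0.201 in N, 144 in B and 215 in S. Itga6, on chromosome 2 (71745616 to 71858416, ENSMUSG00000027111), encodes the alpha 6 integrin chain of hemidesmosomes. Its transcript was 1.49-fold higher in B (49.3) than in S (33.1), the order of the gates. The highest Itga6 level was in the N library, at 115.

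Markers of other cell types were looked at next. Of the lists for mast cells, endothelial cells, pericytes and smooth muscle, and Merkel cells, 0 genes reached a mean of 1. Their most abundant members were Hdc (0 in N, 0.149 in S and 1.05 in B), Ramp2 (2.35 in B and 0.403 in S), Cnn1 (0.243, 0.463 and 0.247 in N, S and B) and Krt8 (at most 0.122). The red blood cell gene Hba-a2 stayed at or below 1.91. Of 12 genes for T and NK cells, Thy1 alone was measured, at 18.3 in N, 4.99 in B and 0.673 in S. The others were at most 1.18 in any library (Cd3e in N, picked after its values were seen), so Thy1 alone does not show T cells. Of 7 measured Langerhans and myeloid cell genes, 4 were lower in B than in N and 5 lower in S, such as H2-Aa, a class II antigen-presenting molecule, at 13.5 in N, 4.81 in B and 4.51 in S. The lysosomal protein gene Cd68, picked after its values were seen, was higher in S, at 6.02 against 1.69 in N. The Schwann cell list had 2 measured genes, of which Erbb3 was at 11.2 in N, 5.80 in S and 4.60 in B. Of the melanocyte list, the transcription factor gene Mitf was measured alone, at 2.08 in N, 34.4 in S and 16.4 in B. Of the fibroblast list, 3 of 15 genes were measured, and all 3 were at least 2-fold higher in B and in S than in N. Col6a1, a collagen VI chain, was at 0.242 in N, 25.9 in S and 13.9 in B.

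**Figure D1:**
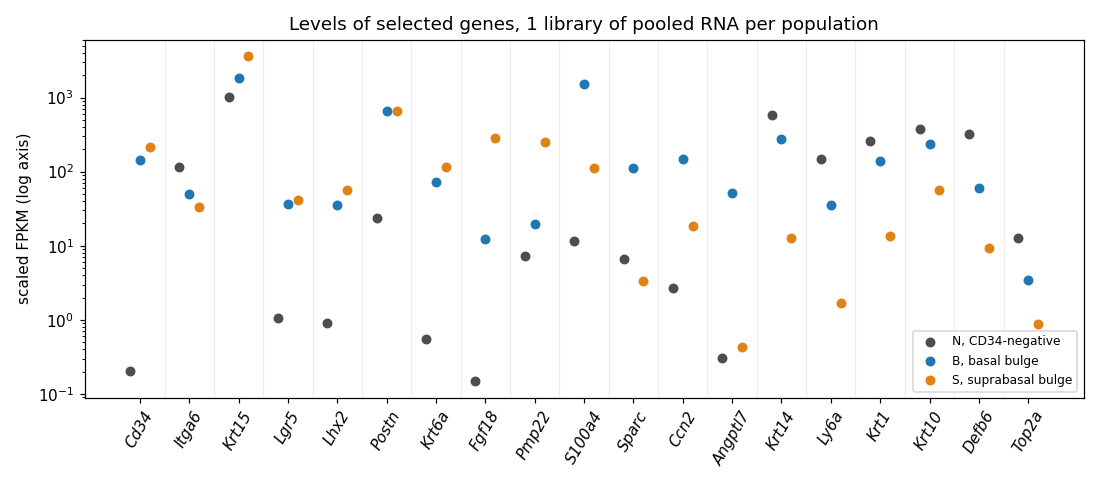
Scaled FPKM (log axis) of 19 genes in the N, B and S libraries, with 1 point per library. Cd34 was at 0.201 in N and at 144 and 215 in B and S, and Krt14 was at 588, 277 and 12.7 in N, B and S.

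In basal bulge cells against CD34-negative cells, most genes known from bulge stem cells were higher and most measured genes of cell division were lower. S100a4, a calcium-binding protein gene, was at 1521 in B and 11.5 in N, a 132-fold difference. Postn, which encodes the matrix protein periostin, was at 654 against 23.6, and the stem cell receptor gene Lgr5 at 36.5 against 1.05. The division gene Top2a, needed to separate chromosomes, went the other way, at 3.44 in B and 12.6 in N.

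Of the 11575 genes measured, 841 were at least 2-fold higher in B and 822 lower. The 10 genes with the largest ratios towards B were S100a4, Cd34, Krt6a, Angptl7, Ccn2, Krt24, Cck, Tgm5, Duoxa1 and Postn. Krt6a, a keratin of the inner bulge layer, was at 72.3 against 0.549. Angptl7, a secreted protein gene, was at 51.2 against 0.307, and Cck, which encodes the peptide cholecystokinin, at 63.9 against 0.762. Ccn2, a matrix protein gene induced by TGF-beta, was at 147 against 2.73. Tgm5, a transglutaminase gene, was at 124 against 2.58. Towards N the 10 genes were Casp4, Ccl27b, Hist1h2bg, Hist1h2bk, Hist1h2bn, Il20ra, Ly6c1, Selenon, Rpl22 and Phf3. Selenon, a selenoprotein gene, was at 2.76 in B and 34.8 in N, and the cytokine receptor gene Il20ra at 3.07 and 22.0. The histone gene Hist1h2bk was at 0.585 in B and 11.3 in N. Rpl22, a ribosomal protein gene, and Phf3 are listed at 0 in B, with 845 and 12.8 in N, and no ratio is given for them.

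The list of bulge stem cell genes had a median log2 ratio of 2.77, with 16 of 18 genes higher and 0 lower. Among the 16 is Cd34, on whose protein the cells were sorted. Among its members Dkk3, a Wnt antagonist relative, was at 39.3 in B and 1.15 in N, and the Wnt inhibitor Sfrp1 at 112 and 6.21. Krt15, the classical bulge keratin, was picked after its values were seen and was at 1855 in B and 1014 in N. Hedgehog pathway genes had a median of 1.22, with 4 of 8 higher, among them the co-receptor genes Gas1 (31.3 against 4.93), Boc (10.7 against 2.06) and Cdon (11.8 against 3.67). BMP and TGF-beta genes had a median of 0.70, with 10 of 26 higher and 1 lower, including the BMP antagonist Grem1 (33.3 against 0.393) and the BMP-induced genes Id1 (21.8 against 4.25), Id2 (55.5 against 3.89) and Id3 (77.9 against 22.7). Wnt inhibitors had a median of 0.57 over 6 genes, with Apcdd1 lower in B (3.26 against 17.9). Basement membrane and hemidesmosome genes had a median of 0.24, with 4 of 24 higher, among them Npnt, the matrix protein nephronectin that anchors the muscle of hair erection (21.2 against 4.34), and Egfl6 (15.1 against 3.68).

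Lists that stood apart on the lower side included S, G2 and M phase genes (median -1.18, 12 of 20 lower), the upper hair follicle (median -1.04, 4 of 8 lower) and Langerhans and myeloid cells (median -1.32, 4 of 7 lower). In the upper follicle list, the defensin gene Defb6 was at 60.3 in B and 326 in N, and Lrig1, which marks upper follicle stem cells, at 10.8 and 34.7. Immediate early and heat shock genes had a median of -0.67, with 2 of 19 lower, including Egr2 (8.96 against 39.3). Interferon response genes had a median of -0.66, with 2 of 10 lower, among them Psmb8, a subunit of the immunoproteasome (5.06 against 14.1). Sebaceous and lipid genes (median -0.72, 1 of 8 lower), tight junction genes (median -0.62, 4 of 10 lower) and differentiation genes (median -0.45, 4 of 20 lower) also stood apart. Without the filter on the mean, the median of the differentiation genes turned slightly to the higher side. Fasn, the fatty acid synthase gene, was at 3.61 against 10.8, and Cldn1, the main claudin of epidermis, at 72.5 against 180.7. Wnt ligands, receptors and targets had a median of -0.51, while their mean was 0.12, because Fzd2 (13.7 against 0.922) and other receptor genes were higher. With a mean of at least 5, which drops the ligands, the median of this list turned to the higher side. Calml3, a differentiation gene, went against its list at 103 in B and 7.38 in N. In all, 14 of 24 lists stood apart.

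With the values as deposited the split was 717 higher and 1097 lower, and after rescaling to the same total it was 1282 higher and 802 lower. Simulated unchanged libraries, with counting error only, gave at most 4 genes in either direction, which leaves out amplification and mouse-to-mouse differences.

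In suprabasal bulge cells against CD34-negative cells, most bulge stem cell genes were higher, and most measured genes of cell division were lower. The inner bulge list was split, with 4 of 7 genes higher and 3 lower, and 5 of 8 interfollicular basal genes and 5 of 8 upper follicle genes were lower. Fgf18, a growth factor gene of the inner bulge layer, was at 282 in S and 0.148 in N. Krt14, the keratin of basal keratinocytes, was at 12.7 in S and 588 in N, a 46.2-fold difference. Krt5, its partner keratin, was picked after its values were seen and was at 959 and 818.

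There were 1107 genes at least 2-fold higher in S than in N and 1260 lower. The genes with the largest ratios towards S were Fgf18, Cd34, Krt6a, Sh3kbp1, Sncg, Myoc, Mme, Pmp22, Lhx2 and Pi15. Krt6a was at 115 against 0.549, and Lhx2, a transcription factor gene of hair follicle stem cells, at 56.1 against 0.911. Pmp22, known as a myelin protein gene, was at 253 against 7.25, and Sncg, which encodes gamma-synuclein, at 91.1 against 0.747. Towards N the largest ratios were those of Ly6a, Krt14, Tnfrsf19, Defb6, Gpha2, Arhgdib, Fcgbp, Ly6d, Serpinb2 and Il33. Ly6a, the Sca-1 surface antigen of interfollicular and upper follicle keratinocytes, was at 1.69 in S and 150.1 in N. Tnfrsf19, a TNF receptor family gene, was at 0.514 and 50.9, and the alarmin gene Il33 at 0.923 and 45.7.

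Bulge stem cell genes had a median of 2.37, with 15 of 18 higher, Cd34 among them. Inner bulge genes had a median of 2.19, with 4 of 7 higher and 3 lower. That median is the ratio of Bmp6 (3.77 in S, 0.0435 in N), a low gene picked after its values were seen. The inner bulge gene Krt17 was lower in S, at 13.6 against 39.95. Wnt inhibitors (median 1.11, 3 of 6 higher and 1 lower, Apcdd1 at 0.443 against 17.9), BMP and TGF-beta genes (median 0.46, 11 of 26 higher and 2 lower) and cell cycle inhibitors (median 0.54, 3 of 13 higher) also stood apart on the higher side. Id2 was at 118 in S and 3.89 in N, while Bmp4, a BMP ligand gene, was at 0.362 and 12.7. Cdkn1b, which encodes the cell cycle inhibitor p27, was at 25.5 and 9.25. Mitochondrially encoded transcripts had a median of 0.66, with 3 of 13 higher, and mt-Cytb was at 5853 against 2335. Some members were far below the others, so their ratios are less certain. Among them, picked after their values were seen, were mt-Co3 (2.33 against 0.552), which is 1 of the 3, and mt-Nd4l (25.2 against 15.5), which gives the median. Nuclear genes of oxidative phosphorylation had a median of -0.05 and did not stand apart.

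The interfollicular basal list had a median of -2.37, with 5 of 8 genes lower, including Ifitm3 (37.9 against 486) and Thbs1, which encodes thrombospondin 1 (0.227 against 10.2). S, G2 and M phase genes had a median of -1.67, with 13 of 20 lower, and the ubiquitin-conjugating enzyme gene Ube2c was at 0.708 in S and 18.1 in N. Pcna, a replication gene of that list, was at 50.9 and 62.3. The upper follicle list had the same median of -1.67, with 5 of 8 lower, and Krt79, a keratin of the follicle opening, was at 2.20 against 37.8. Interferon response genes had a median of -1.43, with 7 of 10 lower, including B2m, the light chain of class I molecules (614 against 2576), and H2-K1 (57.5 against 191). Sebaceous and lipid genes had a median of -1.38, with 5 of 8 lower, and Langerhans and myeloid genes one of -1.40, with 5 of 7 lower. Differentiation genes had a median of -0.85, with 10 of 20 lower and 2 higher, and without the filter on the mean it turned slightly to the higher side. Krt1 (13.3 against 258) and Krtdap (337 against 2868) were lower, and Sbsn, which encodes suprabasin, was higher (460 against 84.9). Immediate early and heat shock genes had a median of -0.59, with 4 of 19 lower, among them Nr4a1 (6.42 against 39.4). In all, 14 of 24 lists stood apart.

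With the values as deposited the split was 856 higher and 1675 lower. After rescaling to the same total it was 223 and 8682, since mt-Tl1 enters the total of S alone.

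**Figure D2:**
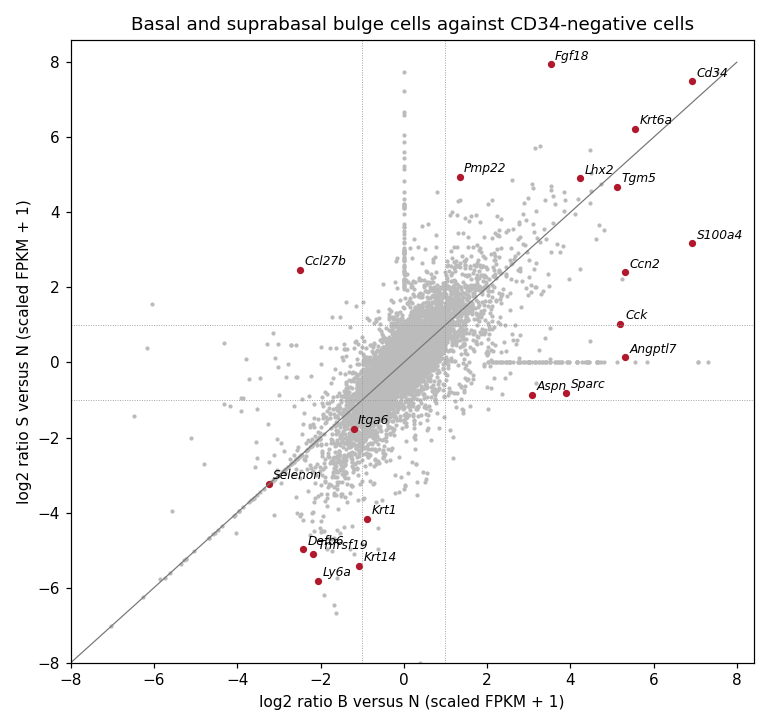
Log2 ratio of B versus N (x axis) against S versus N (y axis) for 11575 genes, 10 of which lie outside the axes, with dotted lines at the 2-fold rule and a diagonal of equal ratios. Points in lines at 0 include genes listed at 0 in both libraries of a ratio, and Fgf18 (282 in S, 12.2 in B) and S100a4 (112 in S, 1521 in B) lie on either side of the diagonal.

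Both bulge populations shared much of their difference from N. There were 533 genes at least 2-fold higher in both B and S than in N, and 652 lower in both. Cd34, Krt6a, Postn, Lgr5, Lhx2, Id2 and Grem1 were among the genes higher in both. Defb6, Ly6a, Krt14, Top2a and Itga6 were among the genes lower in both. Independent lists of these sizes would share 80.4 genes on the higher side and 89.5 on the lower side, and unchanged libraries set against the same N library gave at most 2 with counting error only. As deposited, the counts were 432 higher and 886 lower in both, and on the same total 180 and 786. Part of the excess could come from the shared N library, which could not be split. Without predicted models, small RNAs and mitochondrial genes, 439 genes were higher in both and 424 lower in both. The N library also differed from both B and S in ribosomal RNA (AY036118 at 7503 in N, 42888 in S and 52043 in B) and in small nucleolar RNA. Such a difference in the RNA captured was not separated from a difference between the cells.

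Between the bulge layers, suprabasal cells had higher levels of Fgf18 and Pmp22, and basal cells had higher levels of S100a4, Sparc and Krt14. Fgf18 was at 282 in S and 12.2 in B, and Pmp22 at 253 and 19.9. S100a4 was at 1521 in B and 112 in S, and Sparc, a collagen-binding matrix protein gene, at 112 in B and 3.32 in S. The stem cell genes Postn (657 in S, 654 in B) and Lgr5 (40.8 and 36.5) were at close levels in both.

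There were 450 genes at least 2-fold higher in S and 686 higher in B. The genes with the largest ratios towards S were Ccl27b, Fgf18, Tspan2, Pmp22, Ralgps1, Mcoln3, Smoc1 and Ramp1, with Rpl22 and Phf3 listed at 0 in B. Tspan2, a tetraspanin gene, was at 24.3 in S and 0.918 in B. Ramp1, part of the receptor for the neuropeptide CGRP, was at 26.8 and 2.54. Ccl27b, at 201 and 5.49, has near-identical copies in the genome, so its level is uncertain. Towards B they were Angptl7, Sparc, Krt14, Cck, Aspn, Fcgbp, S100a4, Ly6a, Fam180a and Thbs1. Angptl7 was at 51.2 in B and 0.433 in S, Cck at 63.9 and 2.58, and Aspn, a small matrix proteoglycan gene, at 22.0 and 0.510.

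Inner bulge genes (median 0.66, 3 of 7 higher in S), mitochondrially encoded transcripts (median 0.56, 0 of 13 past the rule), cell cycle inhibitors (median 0.32, 2 of 13) and bulge stem cell genes (median 0.28, 2 of 18 higher in S and 4 in B) stood apart towards S. The mean of the bulge list was -0.30, opposite in sign to its median, because Angptl7, Ccn2 (147 in B, 18.6 in S), Dkk3 (39.3 and 11.1) and Sfrp1 (112 and 32.8) were far higher in B. Towards B stood the interfollicular basal list (median -1.76, 4 of 8), with Krt14 at 277 in B and 12.7 in S. Wnt inhibitors (median -0.80, 3 of 6), interferon response (median -0.73, 1 of 10) and Hedgehog pathway genes (median -0.62, 3 of 8) followed. So did S, G2 and M phase genes (median -0.59, 7 of 20), differentiation genes (median -0.49, 5 of 20), Wnt ligands, receptors and targets (median -0.43, 2 of 16) and sebaceous and lipid genes (median -0.38, 1 of 8). Relative to all genes, the median of the Wnt ligands, receptors and targets turned towards S with a mean of at least 5 and on the same total. Hypoxia and antioxidant genes (median -0.29), the upper follicle list (median -0.26) and basement membrane genes (median -0.18) also stood apart towards B. Krt10, a keratin of differentiating layers, was at 233 in B and 55.9 in S, and the integrin gene Itga3 at 9.63 and 1.64. The thioredoxin reductase gene Txnrd1 was at 33.3 in B and 5.83 in S, while Ndrg1 (10.5 and 33.1) and Egln3 (5.34 and 16.2), both induced by low oxygen, were higher in S. In the Wnt list the receptor genes Fzd1 (33.9 in S, 10.96 in B) and Fzd7 (25.9 and 11.97) were higher in S. In the Notch list, which did not stand apart (median 0.22), Notch1 was at 20.8 in S and 7.93 in B, and the modifier gene Lfng at 0.465 and 15.6. In all, 15 of 24 lists stood apart.

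**Figure D3:**
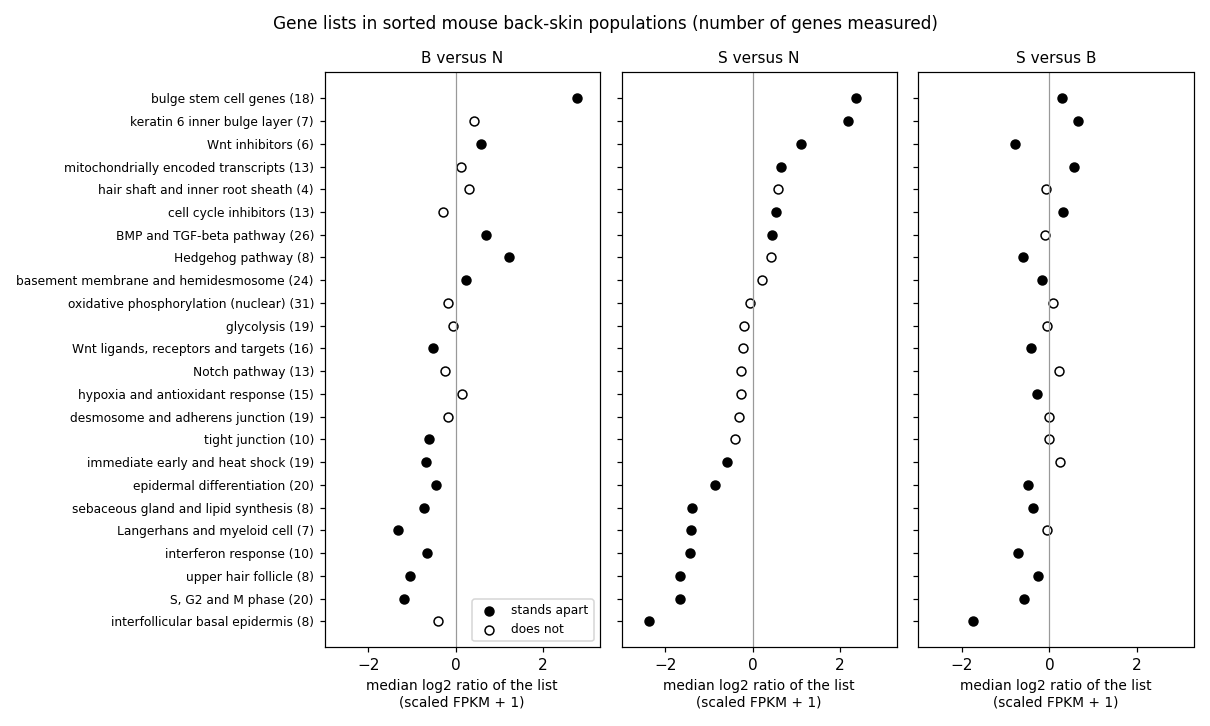
Median log2 ratio (x axis) of the 24 gene lists with at least 4 measured genes, for B versus N, S versus N and S versus B. Filled points stand apart from 10000 matched random lists; the interfollicular basal list lies at -2.37 for S versus N and at -0.41 for B versus N, where it does not stand apart.

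The count of genes higher in B includes genes that were highest in N. When 0.235 of the N level was subtracted from the B library, a choice made after seeing the data, the split was 650 higher in S and 573 higher in B. The ratios of the upper follicle, hypoxia and antioxidant, and bulge stem cell lists then turned their sign relative to all genes, as did those of Ly6a, Defb6, Krt79, Top2a, Apcdd1, Tnfrsf19, Il33, Il20ra and Ly6c1. The subtraction by construction brings a gene below its level in S when its share is under 0.235, so the turns of these single genes do not show which layer had more. The bulge stem cell list turned the other way, towards B, and the remainder of B was divided by what was left of the library, which raises genes nearly absent from N such as Cd34. After rescaling to the same total the split was 82 higher in S and 10251 higher in B.

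The remaining lists did not stand apart in any of the 3 comparisons. Desmosome and adherens junction genes had medians of -0.18 for B versus N, -0.32 for S versus N and -0.01 for S versus B, although Dsg1a was at 89.3 in N, 41.5 in B and 13.4 in S and Ctnnb1 at 66.5, 101.0 and 188. Glycolysis genes had medians of -0.05, -0.19 and -0.04, with the glucose transporter gene Slc2a1 at 49.4 in N, 23.0 in B and 20.997 in S. Nuclear genes of oxidative phosphorylation had medians of -0.18, -0.05 and 0.09. Notch pathway genes had medians of -0.24 and -0.25 against N. Of the hair shaft and inner root sheath list, 4 of 20 genes were measured, with medians of 0.32, 0.59 and -0.09, and Gata3 was at 43.6 in N, 13.2 in B and 8.51 in S.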

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

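All tests in this part were chosen after the results had been seen. In 5 genes B and S lay on opposite sides of N by at least 2-fold each, and the difference was not tested because each population is 1 library. The integrin gene Itgb6 was at 3.32 in N, 8.38 in B and 0.245 in S, with a log2 ratio of S versus B of -2.91. The protease gene Prss23 was at 10.1, 28.9 and 3.61 (log2 ratio -2.70), and Prss23os, an RNA gene that lies within the span of Prss23 and may share its reads, at 10.5, 29.7 and 3.48 (log2 ratio -2.77). The selenoprotein gene Selenov was at 1.24 in N and 5.80 in B and is listed at 0 in S (log2 ratio -2.77 with the pseudocount). Ccl27b went the other way, at 35.5 in N, 5.49 in B and 201 in S (log2 ratio 4.96).

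A gene ID without a symbol, left out of all comparisons (ENSMUSG00000089855, chromosome 10, 105238134 to 105238292, mm10), was at 674 in N, 3384 in S and 3593 in B.

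Most genes far higher in N than in S sat at intermediate levels in B. Over 66 protein-coding genes at least 8-fold higher in N than in S and at 20 or more in N, the share (B minus S, over N minus S) had a median of 0.235, with quartiles of 0.190 and 0.333. This median is the value subtracted from the basal library in the added alternative. Other sets gave other shares, with a median of 0.382 over 10 differentiation genes (quartiles of 0.331 and 0.510). The median was 0.321 over 10 interfollicular basal and upper follicle genes and 0.218 over 13 S, G2 and M phase genes. Cd34 gave 0.329 if its level is taken as equal in bulge cells of both layers, which was not tested. Postn, picked after its values were seen, would give a far lower value (23.6 in N, 654 in B and 657 in S). The median share of 6 genes from the immune cell lists was 0.0558, below the 5th percentile of the 66 genes (0.117). Of the 6 genes, 4 lay below that percentile, while Thy1 (0.245) and H2-Eb1 (0.216, picked after its values were seen) were near the median of the 66 genes. All sets from the lists, these 6 genes included, were taken by a looser rule, at 2-fold over S and with a lower minimum in N. The comparison with the 66 genes is therefore unlike. Among the sets taken by the looser rule the immune median was the lowest, with 0.218 for S, G2 and M phase genes the next. It rests on 6 genes, of which Thy1 and H2-Eb1 lay close to 0.218. It therefore does not decide whether a share of the whole CD34-negative population, all cell types alike, lay in the basal library. CD34-negative keratinocytes or their RNA in the basal library may account for the pattern, and so may expression by the basal bulge cells themselves. The 5th percentile of 0.117 does not separate them, because genes chosen for a low level in S can hardly have a share below 0. Of the genes, 4.55% (Adh7, Rnase4 and Ackr4, picked after their values were seen) had a share above 0.9. The ratio of the upper to the lower quartile of the shares was 1.76, above the highest of 1000 simulations of a single share (1.14). Those simulations hold counting error only and leave out amplification and differences between mice. The explanations could not be told apart, because with 1 library per group the spread of the shares could not be set against the spread between libraries.

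Rpl22 and Phf3 are listed at 0 in B. The lower of their levels in N and S would give 539 fragments for Phf3 in B and 10251 for Rpl22, which argues against too few fragments. A failed estimate for these 2 genes may account for it and stays open, since the files mark no failed values. These were the 2 named genes listed at 0 in B with at least 10 scaled FPKM in both other libraries, and by the same limit there were 0 in N and 0 in S. No biological explanation was tested.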

How the results depend on the processing

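The alternatives for the basal library with 0.235 of the N level subtracted, for genes above 0 in all 3 libraries and for totals without small RNAs and mitochondrial genes were chosen after seeing the data. With no replicates, a count is called moved beyond 1.5 times, a list median beyond 1 SD of matched random medians and a named gene when it falls below 2-fold. Medians and ratios are relative to all genes, since scaling shifts them: values as deposited moved the median of all genes by -0.14 (B versus N) and -0.20 (S versus N), rescaling to the same total by 0.15 (B versus N), -1.43 (S versus N) and -1.60 (S versus B), and totals without small RNAs by -0.11 (B versus N).

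The number of lists apart stayed within 1.5 times under every alternative run, and so did all counts of genes under the values as deposited, upper-quartile scaling, no filter, the highest row per symbol, genes above 0 and totals without small RNAs. Of 514 list medians under the alternatives, 365 stayed, 140 moved and 9 reversed. Of 3291 ratios of named genes, 3122 stayed, 160 moved and 9 reversed.

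Counts are given as total (higher, lower) for B versus N, S versus N and S versus B, then higher and lower in both than in N. A 4-fold threshold gave 483 (288, 195), 821 (361, 460), 379 (148, 231), 119 and 147. A pseudocount of 5 gave 657 (308, 349), 1003 (447, 556), 467 (190, 277), 150 and 283. A mean of at least 5 gave 792 (373, 419), 1157 (546, 611), 580 (239, 341), 274 and 331. These choices make counts smaller by construction. Other alternatives moved part of the counts. A pseudocount of 0.1 gave 1722 for S versus B (1074 lower) and 893 higher in both. Leaving out predicted models, small RNAs and mitochondrial genes gave 527 lower for B versus N, 715 (289, 426) for S versus B and 424 lower in both, since fewer genes enter. Rescaling to the same total gave 1282 higher for B versus N, 8905 (223, 8682) for S versus N, 10333 (82, 10251) for S versus B and 180 higher in both, with mt-Tl1 in the total of S. Subtracting the N share gave 2611 for B versus N (1525 lower).

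Reversed list medians were those of differentiation genes without a filter (0.046 for B versus N and 0.034 for S versus N, with genes near 0 added), Wnt ligands, receptors and targets with a mean of at least 5 (1.55 for B versus N and 0.40 for S versus B) and on the same total (0.18 for S versus B), and bulge stem cell genes on the same total (-0.047 for S versus B). A mean of at least 5 keeps Fzd1, Fzd2, Fzd3, Fzd6, Fzd7, Lrp6 and Wls of the Wnt list and drops its ligands and Axin2. The cause of the reversals on the same total was not tested. Subtracting the N share reversed S versus B for the bulge stem cell (-0.16), upper follicle (0.72) and hypoxia (0.11) lists, and by construction for genes with a share under 0.235, Apcdd1 (0.42), Defb6 (3.26), Il20ra (0.31), Il33 (0.83), Krt79 (0.39), Ly6a (1.32), Ly6c1 (0.42), Tnfrsf19 (0.49) and Top2a (0.12). Under this subtraction 19 list medians stayed, 21 moved and 3 reversed, and 251 ratios of named genes stayed, 15 moved and 9 reversed. No paired analysis was possible because each group has 1 library and no test was run. Depth limits single values below 1 FPKM, where a 2 kb transcript has fewer than 70.6 fragments.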

Other observations

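Gene families outside the fixed lists were looked at after the values had been seen. Of 42 histone genes, 29 were at least 2-fold lower in B than in N (median log2 ratio -1.32) and 33 lower in S (median -1.64), and 0 were higher in either. Most histone mRNAs made for DNA replication lack a poly(A) tail. Small nucleolar RNA, which lacks one too, had a summed deposited FPKM of 215181 in N, 61722 in S and 41475 in B (28.1%, 2.60% and 6.92% of all). Ribosomal RNA, also non-polyadenylated, went the other way, with CT010467.1 at 6061 in N, 52561 in S and 45282 in B. Most measured S, G2 and M phase genes were lower in B and S as well. The reason for the histone difference was not tested. Of 11 measured Skint genes, which encode keratinocyte proteins related to butyrophilins that shape the T cells of the epidermis, 8 were lower in S than in N and 1 was higher. Skint1 was at 87.5 in N, 21.2 in B and 3.77 in S, and Skint4 at 17.4, 15.4 and 45.1. All 6 Ly6 genes were lower in S than in N, and 4 were lower in B, with Ly6d at 736 in N, 206 in B and 27.6 in S. Among 9 S100 genes, S100a6 was at 311 in N, 2119 in B and 4169 in S, while S100a4 was highest in B, at 1521. Ribosomal protein genes had medians of -0.29 for B and -0.32 for S over 75 genes, and 3 and 2 of them were lower by the rule. The 3 for B include Rpl22, which is listed at 0 there and may be a failed estimate.

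The genes named here were chosen after their values were seen. Among 9766 genes with named models, 101 were at least 2-fold higher in B than in both N and S, and 228 were higher in S than in both. The first set held Crip1 (43.2 in N, 164 in S and 444 in B), the chemokine gene Cxcl14 and the adhesion gene Alcam. The second held Them5, Sdc1, which encodes the proteoglycan syndecan 1, and Epcam, an epithelial adhesion gene. The opposite patterns were 21 genes lowest in B and 287 lowest in S.

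Ribosomal RNA of the locus on chromosome 17 differed between libraries, with AY036118 at 7503 in N, 42888 in S and 52043 in B. The mitochondrial gene mt-Co3 was at 0.552 in N, 2.33 in S and 1.17 in B, far below mt-Co1 at 5208, 9538 and 6183.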
